A study of Homo sapiens with 24 samples.

How the data were processed

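Gene expression was measured on Illumina bead arrays hybridised with biotin-labelled RNA from 2 human pancreatic ductal adenocarcinoma cell lines, AsPC-1 and COLO-357. Each line received vehicle or PD-0332991 (palbociclib, an inhibitor of the cyclin D-dependent kinases CDK4 and CDK6) at 5 µM, and RNA was taken at 24 h or 72 h. Per the labels there were 3 biological replicates in each of the 8 groups, 24 arrays in all. The lines were kept in different base media, so cell line and medium cannot be told apart.

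The deposited signal table holds 1 bead-summary intensity per probe and array, linear and without normalisation. Per the file headers a detection p-value stands beside each intensity. The software behind the signals, and any background step in it, is not given in the sources used here. The authors' value table of the same arrays was checked against the signal table, and each intensity was the deposited signal multiplied by 1 factor per array. The array medians of these scaled intensities were 95.87 to 100.3 in AsPC-1, 94.76 to 95.24 in COLO-357 at 24 h and 90.73 to 92.7 in COLO-357 at 72 h. The authors also deposited 6 lists of changed genes, each with the ratio of treated over control. In the 4 drug lists this deposited ratio was checked to lie within 2.86% of the ratio of geometric means of the authors' scaled intensities. The smallest change in those 4 lists was 1.99-fold. The test behind the authors' lists, which gave a parametric p-value, is not given in the sources used here. The other 2 lists compare a cyclin knockdown with its control, and the arrays behind them were not analysed here.

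Signals were background-corrected with the normal-exponential model using the detection p-values, quantile-normalised and converted to log2 with an offset of 16 (neqc in limma 3.58.1, R 4.3.3). Of 47223 probes, 24750 had a detection p under 0.05 on at least 3 arrays and were tested. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

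The files pair probes with gene symbols only in the authors' 6 deposited lists, which name 685 of the tested probes with 605 symbols, and 2 listed probes had no symbol. Of these symbols 462 equal a current RefSeq symbol, 77 equal only an older one and 66 matched neither, and the deposited name was kept. The planned fit of 1 probe per gene was therefore replaced by a test of every probe, so counts are counts of probes. A named gene is represented by its named probe with the highest mean log2 signal over all 24 arrays. Genes have names here because the authors selected them for a change in these same samples (or in the knockdowns). The directions of named genes and the p-values of lists are therefore not independent evidence. Lists were also tested with only the members named through the authors' lists of the other cell line, where at least 3 remained. This choice was made after the names had been seen, and such members were still selected for a response in the other line.

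All 24 arrays were fitted with 1 mean per group (lmFit and eBayes in limma, 16 residual and 5.84 prior degrees of freedom). The contrasts were drug against vehicle in each line at each time, the difference of those effects between times and between lines, 72 h against 24 h in vehicle cultures, and COLO-357 against AsPC-1 in vehicle cultures at 24 h. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all 24750 probes, and a probe was called at an adjusted p under 0.05. The contrasts, the gene lists and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 14 lists with at least 3 named members. Camera with an estimated correlation and fry were the alternatives. Only part of each list was named, with 3 of 36 TGF-beta targets, 8 of 42 mesenchymal, 4 of 45 epithelial and 6 of 32 CDK4/6-RB genes. The 11 of 44 interferon and 3 of 24 antigen presentation genes were all lower in the AsPC-1 knockdown list. Camera sets such selected members against probes that were mostly not selected, which by itself favours small p-values. The tested lists covered DNA replication and S phase, mitosis, DNA repair of S phase, the CDK4/6-RB pathway, mesenchymal genes, epithelial junction and polarity, TGF-beta targets, matrix proteases and invasion, the interferon response, antigen presentation, secreted inflammatory factors, cholesterol synthesis, the unfolded protein response with amino acid stress, and mucins with ductal differentiation genes. The last of these, called mucins below, has 4 named members, of which only MUC5AC is a mucin gene. Marker lists of other pancreatic, stromal and immune cell types had 0 named members, so RNA of other cell types could not be checked. The procedure was tested on simulated data with the spread of these arrays. For the 4 drug contrasts it called 72% to 84% of simulated 2-fold changes and 24% to 32% of 1.5-fold changes. For the 4 differences between times or lines it called 30% to 38% and 0% to 7%. The percentage of recovered changes with the right sign was 100 in each contrast. In the simulation 102 to 121 probes were called per drug contrast, 4 to 8 of them falsely. Per difference 32 to 44 were called, 0 to 5 of them falsely. The real drug contrasts had 1499 to 2900 calls, so the adjusted threshold was stricter in the simulation. Its rates therefore need not hold for the real contrasts.

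For each drug contrast the text draws on up to 10 higher and 10 lower genes with the largest change among called genes that were detected on all 3 arrays of at least 1 group and whose groups did not overlap, leaving out provisional and open-reading-frame symbols. Chance alone separates 3 arrays from 3 in 10% of genes. It also draws on up to 4 called members of each list and on a fixed set of 25 genes, among them CCND1, CCNE2 and SNAI2. Some genes that these rules select are not reported here or drawn in the figures, but stay in the counts and list tests. For the other contrasts it draws on up to 5 genes in each direction. Only named genes could be ranked. Of the probes called with at least a 2-fold drug effect, 341 of 614 had no name in AsPC-1 at 24 h and 230 of 357 at 72 h. In COLO-357 these were 242 of 554 and 261 of 400. Where a probe was at background on all arrays of the dimmer group the fold is a lower bound, taken against the lowest value of any detected probe of the same array where that was higher. A rise or fall with the drug is relative to vehicle cultures of the same time. Errors of log2 fold changes are standard errors of the fit, and errors of group levels are SDs, with n = 3 arrays per group.

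Replicate numbers recur in every group of the labels. Over probes, the residuals of drug and vehicle arrays with the same number correlated at 0.01 to 0.12 in AsPC-1 and at 0.12 to 0.47 in COLO-357. In COLO-357 the highest correlation with a different number was -0.26 and -0.2 for replicate 2, whose own pairs had 0.47 and 0.38, but 0.11 to 0.18 for replicates 1 and 3, whose own pairs had 0.12 to 0.21. Pairing was therefore clear for replicate 2 of COLO-357 only, and a replicate block was used as an alternative only. COLO-357 arrays at 24 h had higher raw median signals (109.9 to 133) than those at 72 h (85.5 to 92.4). Time and a possible hybridisation batch cannot be told apart in that line, while each drug effect lies within 1 such set. The alternatives changed the background correction, the offset, the scaling, the detection filter, the treatment of several probes of a gene, the arrays in the fit, a replicate block, array weights and the threshold, and left out each array in turn. A block by beadchip was not run because chip positions were not used here.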

Results

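Expression was profiled on 24 arrays in 8 groups of 3, formed by cell line, treatment and time. Between 16440 and 20697 probes were detected per array. The first principal component held 73.5% of the variance and separated the cell lines. The spread between replicates had a median SD of 0.248 log2 in AsPC-1 vehicle cultures at 24 h, and of 0.15 to 0.172 in the other groups.

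The comparison of drug with vehicle at 24 h in AsPC-1 asked which transcripts respond first to CDK4/6 inhibition. CENPA, which encodes the centromeric histone H3 variant, fell by 3.47 ± 0.23 log2 (adjusted p = 1.5e-09), and KIF20A, a kinesin of cytokinesis, fell by 3.05 ± 0.22 (adjusted p = 3.7e-09). Among genes of S phase entry, CCNE2 (cyclin E2, a CDK2 partner), detected on 1 of 3 treated arrays, fell by 3.05 ± 0.28 (adjusted p = 8.8e-08), and RRM2, a subunit of the enzyme that makes deoxynucleotides, fell by 2.61 ± 0.24. CDC25A, a phosphatase that activates CDK2, was at background on all 3 treated arrays and at least 5.23-fold lower. Members of the cholesterol synthesis list also fell, with ACAT2 lower by 3.59-fold and INSIG1 by 3.4-fold. Asparagine synthetase ASNS rose by 1.94 ± 0.15 (adjusted p = 6.8e-09) and the serine synthesis enzyme PSAT1 by 1.59 ± 0.16. The cholesterol exporter ABCA1, detected on 1 of 3 vehicle arrays, rose by 2.37 ± 0.22. CCND1 (0.33, adjusted p = 0.11) did not pass the test.

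Of the 49 named mitosis genes, 49 were lower in AsPC-1 at 24 h (49 adjusted over the list alone), with a median of -1.91 log2 and a camera adjusted p of 1.1e-86. Of 22 DNA replication genes 21 were lower (22 adjusted over the list alone, median -1.62, adjusted p = 2.1e-46). DNA repair genes (9 of 9 lower, median -1.31, adjusted p = 9.9e-18), the CDK4/6-RB pathway (5 of 6 lower, median -1.54, adjusted p = 7.1e-10) and cholesterol synthesis (6 of 6 lower, median -1.29, adjusted p = 1.8e-12) followed. The amino acid stress list was higher (median 1.05, adjusted p = 3.7e-06, with 2 of 4 higher and 4 adjusted over the list alone). These calls held with an estimated correlation. The members were selected by the authors on these samples, so the counts are not independent evidence. With only members named through COLO-357, themselves selected for a response in that line, the mitosis list had 49 of 49 lower. The replication list then had 19 of 20 lower. The mesenchymal list had 2 of 8 higher, ACTA2 (smooth muscle actin) by 1.19 and the repressor SNAI2 by 0.79, with adjusted p = 0.025. It had adjusted p = 0.085 with an estimated correlation, 0.09 without vehicle replicate 2 and 0.4 with members named through COLO-357. The epithelial list had 2 of 4 lower, among them CLDN7, and adjusted p = 0.12, or 0.025 without PD replicate 2 and 0.59 without vehicle replicate 1. TGF-beta targets (adjusted p = 0.19), matrix proteases (0.88), the interferon response (0.073), antigen presentation (0.91), inflammatory factors (0.19) and mucins (0.37) did not pass. In all, limma called 2900 probes, 1468 higher and 1432 lower, and 614 of them changed at least 2-fold, 203 up and 411 down. The split depended on scaling, with 2061 higher and 833 lower in the authors' scaled values. Fitting only the groups compared left 674 probes, 230 higher and 444 lower, and an adjusted p under 0.01 left 645 higher and 838 lower.

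COLO-357 was compared in the same way at 24 h. The mitotic genes fell again: KIF20A fell by 3.5 ± 0.22 log2 (adjusted p = 6.4e-10), CDCA3, a trigger of mitotic entry, fell by 3.29 ± 0.2 (adjusted p = 4.7e-10) and the mitotic kinase gene AURKB fell by 2.48 ± 0.2. HMGB2, a chromatin protein of dividing cells, fell by 2.8 ± 0.2. Among S phase genes RRM2 fell by 1.91 ± 0.24, and CCNE2 fell by 1.4 ± 0.28 (adjusted p = 0.0017). MXD4, a partner of MAX that opposes MYC, rose by 2.38 ± 0.2 (adjusted p = 2.4e-08), YPEL5 rose by 2 ± 0.18, and ABCA1 rose by 1.6 ± 0.22. The TGF-beta target PMEPA1 rose by 1.18 ± 0.16 and ACTA2 by 1.34 ± 0.27. CCND1 passed narrowly (0.4, adjusted p = 0.049) and lost the call on leaving out any 1 of the 6 arrays, with adjusted p up to 0.16. SNAI2 (0.49, adjusted p = 0.073) did not pass, but did with a replicate block (adjusted p = 0.041). SNAI2 also passed without vehicle replicate 2 (adjusted p = 0.008).

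In COLO-357 at 24 h, 49 of 49 mitosis genes were lower (49 adjusted over the list alone, median -1.88, adjusted p = 1.3e-90), as were 22 of 22 replication genes (22 adjusted over the list alone, median -1.15, adjusted p = 1e-38). DNA repair genes (9 of 9 lower, median -1.3, adjusted p = 5.2e-19) and the CDK4/6-RB pathway (5 of 6 lower, median -1.27, adjusted p = 7.3e-08) were lower too. The named members were selected by the authors on these samples or the knockdowns. With members named through AsPC-1 alone 43 of 43 mitosis genes and 19 of 19 replication genes were lower. The mesenchymal list was higher (2 of 8, 5 adjusted over the list alone, median 0.51, adjusted p = 0.0049), as were interferon response genes (5 of 11 higher and 1 lower, adjusted p = 0.013) and the amino acid stress list (2 of 4, 3 adjusted over the list alone, adjusted p = 0.0076). TGF-beta targets went from adjusted p = 0.0055 to adjusted p = 0.056 with an estimated correlation, matrix proteases from 0.031 to 0.056, cholesterol synthesis from 0.013 to 0.2 and the epithelial list from 0.028 to 0.091. The epithelial list also had 0.051 without vehicle replicate 2 and 0.056 without PD replicate 3. Antigen presentation (adjusted p = 0.29), inflammatory factors (0.21) and mucins (0.05) did not pass. The fit called 2796 probes, 1366 higher and 1430 lower, with 174 up and 380 down at least 2-fold, and 1840 without vehicle replicate 1. In the authors' scaled values 1067 were higher and 1915 lower. Across the lines the 24 h effects correlated over probes (r = 0.54, probes are not independent replicates): 430 probes were higher in both lines, 697 lower in both and 7 opposite, where independence would give 81, 82.7 and 164.

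**Figure D1:**
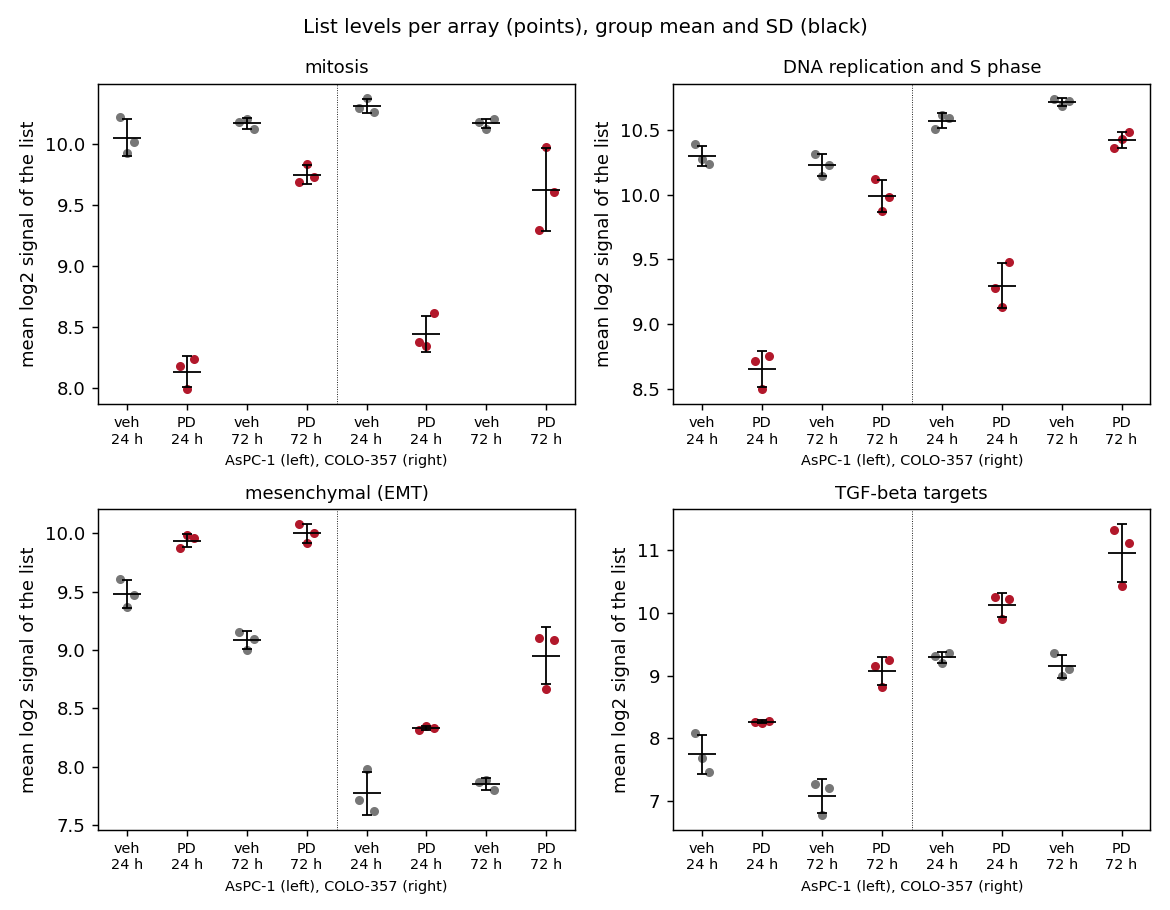
Mean log2 signal of the named members of 4 lists on each array (points), with group mean and SD in black (n = 3), vehicle in grey and PD-0332991 in red. The mitosis list has a median change of -1.91 log2 in AsPC-1 and -1.88 in COLO-357 at 24 h, against -0.43 and -0.55 at 72 h.

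The 72 h comparison in AsPC-1 asked which transcripts differ after longer inhibition. The carboxypeptidase gene CPA4 rose by 3.75 ± 0.44 log2 (adjusted p = 8.2e-06) and the tissue factor gene F3 by 2.56 ± 0.23. The basement membrane collagen gene COL4A1, at background on all 3 vehicle arrays, was at least 4.09-fold higher. CYR61 rose by 2.01 ± 0.29, the urokinase gene PLAU by 1.49 ± 0.21, SNAI2 by 1.29 ± 0.17 and the chemokine gene IL8 by 1.57 ± 0.24, all relative to vehicle at 72 h. From 24 h to 72 h the mean log2 level of SNAI2 went from 9.4 to 9.37 in treated and from 8.61 to 8.07 in vehicle cultures, with 9.21 to 9.39 and 8.52 to 7.82 for IL8, and 11.05 to 11.3 and 10.68 to 9.8 for PLAU. ASNS stayed higher at 2.48 ± 0.15. GPX2, a glutathione peroxidase, fell by 3.38 ± 0.2 (adjusted p = 6.5e-10), the matrix protease MMP7 fell by 2.03 ± 0.25, and the junction gene CLDN7 fell by 1.31 ± 0.13. Vehicle levels also rose from 24 h to 72 h, from 6.91 to 9.83 for GPX2 and from 8.5 to 10.43 for MMP7, whose treated level went from 7.51 to 8.4. CLDN1 of the list that holds CLDN7 rose (0.93, adjusted p = 0.035) but lost the call without any 1 vehicle array, PD replicate 1 or PD replicate 3, with adjusted p up to 0.12. The brush border gene VIL1 and the interferon-induced ligase HERC5, at background on all 3 treated arrays, were at least 3.6-fold and at least 3.24-fold lower, and the vehicle level of VIL1 went from 5.81 at 24 h to 7.33 at 72 h. KIF20A was still lower, having dropped by 1.03 ± 0.22. CCNE2 did not pass (adjusted p = 0.63). CCND1 rose by 0.53 (adjusted p = 0.016) but lost the call without vehicle replicate 2, vehicle replicate 3 or PD replicate 3, with adjusted p up to 0.08.

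In AsPC-1 at 72 h all 3 named TGF-beta targets were higher (3 adjusted over the list alone, median 2.47, adjusted p = 8e-09), as were 4 of 4 amino acid stress genes (median 1.6, adjusted p = 1.5e-13). These are 3 of 36 and 4 of 30 fixed genes, named because they changed, so neither p-value is independent evidence. The TGF-beta median is the value of COL4A1, at background on all 3 vehicle arrays, so its size is not exact. The interferon response was lower (6 of 11, 8 adjusted over the list alone, median -0.61, adjusted p = 2.8e-08). Its 11 named members, of 44 fixed, were all lower in the authors' AsPC-1 knockdown list, with deposited ratios of 0.19 to 0.48. So were the 3 named antigen presentation genes (0.4 to 0.49). The test thus covers genes selected with a fall, not the whole response. The mesenchymal list had 4 of 8 higher and 1 lower (5 and 1 adjusted over the list alone, median 1.2, adjusted p = 5.9e-06), but its 4 members named through COLO-357 had adjusted p = 0.15, and its named members were selected on these samples or the knockdowns. Between treated cultures at 72 h and 24 h it had 0 of 8 higher and a median of 0.03. Mitosis genes were less affected than at 24 h, with 10 of 49 lower (21 adjusted over the list alone, median -0.43, adjusted p = 1.5e-13, and adjusted p = 0.1 with an estimated correlation). Replication genes had 2 of 22 lower (5 adjusted over the list alone, median -0.18, adjusted p = 0.00013, and adjusted p = 0.15 with an estimated correlation). Calls of the epithelial list (2 of 4 lower and 1 higher, median -0.53, adjusted p = 0.019), DNA repair (0.014) and antigen presentation (0.0042) were also lost, at adjusted p = 0.1, 0.16 and 0.066 with an estimated correlation. The list of mucins with ductal differentiation genes was lower and kept its call (0.014 and 0.049). Its largest fall was in VIL1 (-2.21 log2), while its mucin gene MUC5AC did not pass (0.1, adjusted p = 0.94 by limma). The CDK4/6-RB pathway (0.84), matrix proteases (0.56), inflammatory factors (0.14) and cholesterol synthesis (0.56) did not pass. The fit called 1499 probes, 808 higher and 691 lower, and 357 changed at least 2-fold. The count was 831 without vehicle replicate 2, 912 without PD replicate 1 and 951 without PD replicate 3.

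In COLO-357 at 72 h the TGF-beta target PMEPA1 rose by 2.29 ± 0.16 log2 (adjusted p = 2.3e-08) and CPA4 by 2.34 ± 0.44. The caveolae gene CAV1 rose by 2.05 ± 0.3 and the ecto-nucleotidase gene NT5E by 1.77 ± 0.22. MMP7 rose by 1.98 ± 0.25, TXNIP, an inhibitor of thioredoxin, by 2.17 ± 0.21, CCND1 by 0.83 ± 0.13 and SNAI2 by 0.98 ± 0.17. MXD4 stayed higher at 2.39 ± 0.2. The caspase gene CASP9 fell by 2.26 ± 0.18 (adjusted p = 8.5e-08), the mucin gene MUC5AC fell by 1.88 ± 0.32, and IGFBP3, which binds insulin-like growth factors, fell by 1.45 ± 0.19. SPC25, a kinetochore gene, fell by 1.27 ± 0.19, and CCNE2 did not pass (adjusted p = 0.85).

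Of 8 mesenchymal genes in COLO-357 at 72 h, 7 were higher and 1 lower (7 and 1 adjusted over the list alone, median 1.24, adjusted p = 6e-07), and with members named through AsPC-1 6 of 6 were higher (adjusted p = 3.9e-09). TGF-beta targets (3 of 3 higher, median 2.29, adjusted p = 2.4e-06), matrix proteases (3 of 4, median 1.66, adjusted p = 3.5e-05) and amino acid stress genes (2 of 4, adjusted p = 2e-04) were higher. COL4A1 among the TGF-beta targets (0.61 log2, adjusted p = 0.017) lost its call without vehicle replicate 2 or 3 or PD replicate 1 or 3, with adjusted p up to 0.094. The named members of these lists were selected on these samples or the knockdowns. The cross-line counts avoid selection on the same line only. Their members were still selected for a response to the drug or a knockdown in the other line. Such counts show that changes of selected genes recur, not that a whole list shifts. Mitosis genes had 25 of 49 lower (33 adjusted over the list alone, median -0.55, adjusted p = 2.6e-16, and adjusted p = 0.078 with an estimated correlation). The mean level of this list was 9.295, 9.974 and 9.606 on treated replicates 1, 2 and 3, with an SD of 0.34 against 0.04 to 0.15 in the other groups. Its adjusted p ranged from 1.2e-24 without PD replicate 2 to 7.5e-10 without PD replicate 1. Replication genes had 5 of 22 lower (7 adjusted over the list alone, median -0.24, adjusted p = 8.7e-05, and adjusted p = 0.15 with an estimated correlation). DNA repair kept its call (3.5e-05 and 0.043), and cholesterol synthesis did not (3e-05, and adjusted p = 0.069 with an estimated correlation). The epithelial list (0.71), interferon response (0.097), antigen presentation (0.6), inflammatory factors (0.7), mucins (0.81) and the CDK4/6-RB pathway (0.78) did not pass. The fit called 2791 probes, 1420 higher and 1371 lower, and 400 changed at least 2-fold, 268 up and 132 down. It called 1705 without PD replicate 1, 1710 without PD replicate 3 and 4823 with array weights. The authors' scaled values gave 734 higher and 5139 lower. Between lines the 72 h effects correlated at r = 0.28 over probes, with 257 higher in both, 165 lower in both and 44 opposite, where independence would give 46.4, 38.3 and 84.4.

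**Figure D2:**
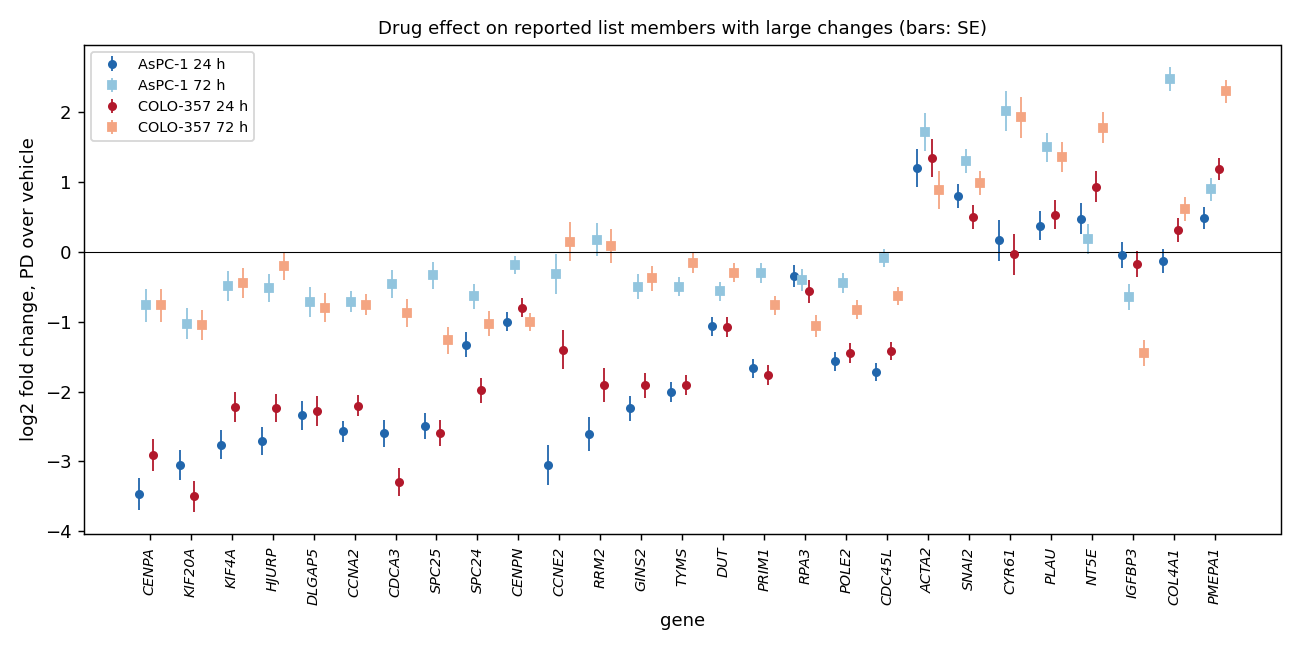
Log2 fold change of drug over vehicle, with its SE, for 27 members of the mitosis, replication, mesenchymal and TGF-beta lists in both lines at both times. KIF20A lies at -3.05 and -3.5 at 24 h and at -1.03 and -1.05 at 72 h, while PMEPA1 reaches 2.29 in COLO-357 at 72 h. Points are fitted values, also where a probe was at background.

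The difference of the drug effect between 72 h and 24 h asked whether the response lasts. In AsPC-1 the effect moved up for RRM2 (2.78 ± 0.34 log2, adjusted p = 4.5e-05), CCNE2 (2.73, detected on 1 of 3 treated arrays at 24 h) and CENPA (2.7), genes of S phase entry and the centromere that had fallen at 24 h. CDC25A (adjusted p = 6.9e-06) and COL4A1 (adjusted p = 1.6e-06) moved up too, by amounts that are not exact because 1 and 2 of their 4 groups were at background. GPX2 moved down (-2.18 ± 0.29, adjusted p = 7.8e-05). In COLO-357 the mitotic genes KIF20A (2.46 ± 0.3, adjusted p = 0.00011), CDCA3 (2.42) and BIRC5, which encodes survivin (2.25), moved up, while the junction gene TJP3 (-1.72, adjusted p = 0.00029) and CASP9 (-1.61) moved down. Of 49 mitosis genes 46 moved up in AsPC-1 (49 adjusted over the list alone) and 40 in COLO-357 (47 adjusted over the list alone), and with members named through the other line 46 of 49 and 37 of 43. Treated cultures at 72 h had higher mitosis genes than treated cultures at 24 h in 49 of 49 and 45 of 49 cases. Not every list that moved up did so in treated cultures: the AsPC-1 amino acid stress list moved up by a median of 0.54, while treated cultures differed by -0.07. Limma called 762 probes in AsPC-1, 466 up and 296 down, and 456 in COLO-357, 310 up and 146 down. The AsPC-1 count was 489 without vehicle 72 h replicate 2 and 499 without PD 72 h replicate 1. It was 365 when only the groups compared were fitted, 466 with 75th percentile scaling and 450 in the authors' scaled values. The COLO-357 count was 271 without vehicle 24 h replicate 1, 296 without PD 24 h replicate 2, 274 without vehicle 72 h replicate 2 and 276 without PD 72 h replicate 3. In the authors' scaled values COLO-357 had 208 up and 1004 down, and array weights gave it 1239 probes.

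The difference between lines asked where COLO-357 responds otherwise than AsPC-1, in different media. At 24 h the effect was higher in COLO-357 for the adhesion gene CEACAM1 (1.94 ± 0.34 log2, adjusted p = 0.0069), the interferon-induced IFIT3 (1.86 ± 0.32, adjusted p = 0.0062) and the sterol gene TMEM97 (1.37), and lower for SEL1L3 (-1.4, adjusted p = 0.0036). At 72 h it was higher for MMP7 (4.02 ± 0.35, adjusted p = 5.3e-07) and GPX2 (3.49 ± 0.29, adjusted p = 3.2e-07), and lower for DUSP1, a phosphatase of MAP kinases (-2.46 ± 0.3, adjusted p = 4e-05), and CASP9 (-2.15). Of 49 mitosis genes 0 differed between lines at 24 h by limma (1 up and 1 down adjusted over the list alone) and 1 at 72 h, and the list's median of 0.03 at 24 h became -0.28 in the authors' scaled values. The interferon response was relatively higher in COLO-357 at both times (medians 0.42 and 0.81, adjusted p = 2.3e-05 and 1e-08). Its named members were all lower in the AsPC-1 knockdown list, so this difference is not independent of their selection. Limma called 175 probes at 24 h, 102 up and 73 down, and 836 at 72 h, 477 up and 359 down. With a replicate block the 24 h count was 324, with an offset of 50 it was 304, and fitting only the groups compared left 41. Array weights gave 1719 at 72 h. The 24 h count was 267 without AsPC-1 vehicle replicate 2, 102 and 89 without AsPC-1 PD replicates 1 and 2, 88, 111 and 80 without COLO-357 vehicle replicates 1, 2 and 3, and 91 and 70 without COLO-357 PD replicates 1 and 3. The 72 h count was 499 without AsPC-1 vehicle replicate 2, 499 without AsPC-1 PD replicate 1 and 485 without COLO-357 PD replicate 3. The authors' scaled values gave 85 up and 276 down at 24 h, and 305 up and 2684 down at 72 h with the median of all probes at -0.116.

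Vehicle cultures at 72 h and 24 h served as the control for time. Of the probes called with at least a 2-fold change, 99 of 128 in AsPC-1 and 497 of 541 in COLO-357 had no name. In AsPC-1 the defensin gene DEFB1 rose by 3.08 ± 0.32 log2 (adjusted p = 1.7e-05), GPX2 by 2.92 ± 0.2 (adjusted p = 3.6e-08) and MMP7 by 1.93 ± 0.25, and the sterol reductase gene DHCR7 fell by 1.02 ± 0.15. CYR61 fell by 1.38 (adjusted p = 0.012, and 0.075 without vehicle 72 h replicate 2). In COLO-357 the myelin gene PMP22 rose by 1.52 ± 0.15 (adjusted p = 1.8e-06) and the peroxisomal oxidase gene ACOX2 by 1.5 ± 0.2, while the noncoding RNA BCYRN1 fell by 1.69 ± 0.21. Limma called 535 probes in AsPC-1, 335 up and 200 down, and 4358 in COLO-357, 2420 up and 1938 down. The AsPC-1 count was 861 without 24 h replicate 2, 145 without 72 h replicate 2 and 314 without 72 h replicate 3, and the COLO-357 count was 2799 without 72 h replicate 2. Fitting only the groups compared left 3 probes in AsPC-1, and array weights gave 350. In AsPC-1 the authors' scaled values gave 739 up and 50 down, and 75th percentile scaling 237 up and 70 down. In COLO-357 the authors' scaled values gave 2208 up and 3036 down, and array brightness differs between its times.

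Vehicle cultures at 24 h gave the baseline difference of the lines. Of the 5696 probes called with at least a 2-fold difference, 5417 had no name. The genes given are therefore the largest among named probes only, which were selected for a drug or knockdown response. COLO-357 had higher GPX2 (7.31 ± 0.2 log2, adjusted p = 2.7e-18), higher AKR1B10, an aldo-keto reductase (6.6 ± 0.17), and higher ALDH1A1, a retinal dehydrogenase (4.81 ± 0.29). AsPC-1 had higher CEACAM1 (-6.15 ± 0.24, detected on 2 of 3 COLO-357 arrays) and the cytokine gene IL32 (-4.22 ± 0.18). Limma called 12924 probes, 6889 higher and 6035 lower in COLO-357. The authors' scaled values gave 10427 higher and 3742 lower with a median of 0.144 over all probes, and 75th percentile scaling gave 6655 and 10296 with a median of -0.269.

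The authors' own lists were set beside these fits, which share the arrays. Of 209 probes listed for AsPC-1 at 24 h, 207 were called in the listed direction, as were 105 of 107 at 72 h, 296 of 298 for COLO-357 at 24 h and 224 of 229 at 72 h. Of the 209 AsPC-1 probes at 24 h, 183 were called in the same direction in COLO-357, whose arrays had no part in that list, and 252 of the 298 COLO-357 probes in AsPC-1, with 0 opposite. At 72 h it was 58 of 107 AsPC-1 probes in COLO-357, with 3 opposite, and 67 of 229 COLO-357 probes in AsPC-1, with 6 opposite. The authors also deposited 2 knockdown lists whose headers name no cyclin, with the cell line read from the sheet's letter, and CCND1 (cyclin D1) had a deposited ratio of 0.46 in AsPC-1 and 0.37 in COLO-357. DUSP1 had a deposited ratio of 2.06 on the linear scale in the AsPC-1 knockdown. With the drug at 72 h it rose by 2.04 on the log2 scale, so the 2 figures are not like sizes. COL4A1 had a deposited ratio of 0.19 and rose with the drug at 72 h. Of 95 probes of the AsPC-1 knockdown list, 35 were called in the same direction and 8 in the opposite direction with the drug at 72 h, against 15 and 4 at 24 h. Of 22 probes of the COLO-357 knockdown list, 5 were called in the same and 4 in the opposite direction at 72 h, and 6 and 1 at 24 h.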

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

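All 3 tests of AsPC-1 vehicle replicate 1, the per-line tests of shared array noise, the list medians in other scaling, the medians of treated cultures alone and the breakdown of splits by whole labels were chosen after the result was seen. Every result in the next 4 paragraphs stands out because the drug effect differed between times or between lines in a test of the difference itself.

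Between 72 h and 24 h in AsPC-1 the drug effect differed for 762 probes. It moved up for CDC25A (2.95 log2), RRM2 (2.78), CCNE2 (2.73), CENPA (2.7) and COL4A1 (2.6), and down for GPX2 (-2.18), TMEM86B (-2.12), HBA1 (-1.95), MYO1A (-1.87) and GOLT1A (-1.75). CDC25A and COL4A1 had 1 and 2 of their 4 groups at background, so the sizes and ranks of these differences are not exact. TMEM86B lost its call in 6 of 12 fits that left out 1 array, with adjusted p up to 0.12, and the HBA1 probe was not checked for cross-hybridisation with HBA2. List medians moved up for DNA replication (1.43), mitosis (1.47), DNA repair (1.2), the CDK4/6-RB pathway (1.5), TGF-beta targets (1.39), cholesterol synthesis (1.39) and amino acid stress (0.54). They moved down for the interferon response (-0.59) and antigen presentation (-0.56, adjusted p = 0.093 with an estimated correlation). Treated cultures alone, 72 h against 24 h, had medians of 1.31, 1.6, 1.12, 1.41, 0.36, 0.75 and -0.07 for the lists that moved up, and of -0.21 for both that moved down. The amino acid stress list thus moved through its vehicle cultures, whose mean level was 10.28 at 24 h and 9.75 at 72 h.

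Between times in COLO-357 the effect differed for 456 probes. It moved up for KIF20A (2.46), CDCA3 (2.42), CKAP2L (2.39), PSRC1 (2.3) and BIRC5 (2.25), and down for MUC5AC (-1.77), CAPN12 (-1.74), TJP3 (-1.72), CASP9 (-1.61) and ACOX2 (-1.56). MUC5AC lost its call in 8 of 12 fits that left out 1 array, with adjusted p up to 0.15. List medians moved up for DNA replication (0.94), mitosis (1.31), DNA repair (0.8), the CDK4/6-RB pathway (1.06), mesenchymal genes (0.81), TGF-beta targets (1.11) and matrix proteases (1.15), and down for cholesterol synthesis (-0.29, adjusted p = 0.36 with an estimated correlation). Treated cultures alone had medians of 1.02, 1.17, 1.1, 1.06, 0.58, 0.49 and 1.02, and of -0.4 for cholesterol synthesis.

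Between lines at 24 h the effect differed for 175 probes. It was higher in COLO-357 for CEACAM1 (1.94), CYP3A5 (1.91), IFIT3 (1.86), GPX2 (1.4) and TMEM97 (1.37), and lower for SEL1L3 (-1.4), GTSE1 (-1.38), NEURL1B (-1.35), GALNT9 (-1.24) and MFAP5 (-1.06). Of these, CYP3A5 lost its call in 11 of 12 fits that left out 1 array, NEURL1B and MFAP5 in 10, GPX2 in 7 and GALNT9 in 1. GALNT9 was detected on 1 of 3 arrays in each COLO-357 group, so the size of its difference is not exact. List medians were higher for DNA replication (0.28), the CDK4/6-RB pathway (0.16), the epithelial list (0.82), the interferon response (0.42), cholesterol synthesis (1.04) and mucins with ductal differentiation genes (0.72), and lower for amino acid stress (-0.71). With an estimated correlation the first 2 had adjusted p = 0.14 and 0.29, and in the authors' scaled values their medians were -0.01 and -0.2.

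Between lines at 72 h the effect differed for 836 probes. It was higher in COLO-357 for MMP7 (4.02), GPX2 (3.49), CYP3A5 (3.1), LFNG (2.92) and PCDH7 (2.91), and lower for DUSP1 (-2.46), CASP9 (-2.15), CA2 (-2.14), CADM4 (-2.09) and MFAP5 (-2.05). List medians were higher for the epithelial list (0.56), matrix proteases (0.21), the interferon response (0.81) and antigen presentation (0.9), and lower for cholesterol synthesis (-0.8) and amino acid stress (-0.99). With an estimated correlation the epithelial list (adjusted p = 0.085), matrix proteases (0.073), antigen presentation (0.085) and cholesterol synthesis (0.16) lost their calls. Line and medium cannot be separated, and a biological difference between the lines stays open and untested.

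The drug and vehicle labels were also regrouped within each pair of groups, in 100 of 200 distinct ways with the real one included. For the difference between times in AsPC-1, 9 of 100 splits gave at least the real 762 probes, the highest other 3700. In COLO-357 it was 13 of 100 against 456, the highest other 4841. Between lines it was 13 of 100 at 24 h against 175, the highest other 4632, and 4 of 100 at 72 h against 836, the highest other 3391. The share was under 0.05 at 72 h between lines only. It cannot decide on a chance division of the arrays for any of these contrasts, because some splits keep a whole drug effect in. The splits that call several times the real count point to a structure of the samples: in all of the other splits as large (8, 12, 12 and 3) the labels of 1 of the pairs were whole or wholly turned, so its drug effect stayed in. Among the 80 splits that broke both pairs the highest counts were 11, 137, 3 and 1, against the real 762, 456, 175 and 836. Those splits mix drug and vehicle arrays within groups, which also raises the spread, so they do not settle the question.

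For comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05, and the real split alone (1 of 10) reached its count. The real and highest other counts were 2900 and 46 (AsPC-1 at 24 h), 1499 and 2 (AsPC-1 at 72 h), 2796 and 1 (COLO-357 at 24 h), and 2791 and 13 (COLO-357 at 72 h). In COLO-357 the splits that part all 3 pairs of arrays with the same replicate number, as the real one does, gave 0 at both times, and the higher values came from splits that part 1 pair. For vehicle cultures over time they were 535 and 6 in AsPC-1 and 4358 and 0 in COLO-357, and for the baseline 12924 and 1.

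The first pattern weighed is AsPC-1 vehicle replicate 1 at 24 h, whose mean correlation with its group was 0.972. RNA of the other line is argued against, since 87 probes bright only in COLO-357 had a median excess of -0.016 log2 (-0.056 to 0.014). Exchange with a treated array of 24 h is argued against too, since its mitosis list lay 2.08 log2 above the mean of those 3 arrays. Treated arrays of 72 h were not part of this test. Their mean level of the list was 9.75, near the 10.05 of the vehicle group at 24 h. The list therefore cannot decide on an exchange with 1 of them. With 75th percentile scaling, mean-intensity bins explained 9.29% of the variance of the deviations of replicate 1 (8.4 to 9.64). This lies between the bounds set, so intensity-dependent scaling cannot be told apart from other causes there. In the quantile-normalised values used for the results the bins explained 3.78%, so little of the deviation in those values follows mean intensity. No biological explanation was tested.

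The second pattern is COLO-357 replicate 2, whose deviations from the other replicates correlated at 0.35 to 0.47 between the 4 groups, with AGR2 lower by a mean of -1.68 log2 and OPN3 higher by 1.53. With 75th percentile scaling, mean-intensity bins explained 1.51% of their variance. The 16 probes bright only in AsPC-1 had a median excess of 0.008 log2 (-0.098 to 0.068). These values argue against intensity-dependent scaling and against RNA of the other line as causes. A culture further along may contribute, but its correlation with the vehicle change of AsPC-1 was 0.098 (0.062 to 0.126), too near the bound of 0.1 to decide.

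The third pattern is that the 72 h drug effect ran against the change of vehicle cells over time, at r = -0.41 over probes in AsPC-1 and -0.19 in COLO-357. Both contrasts share the 72 h vehicle arrays, which alone gives -0.5 in simulations without any effect. With different vehicle arrays in each contrast the covariance was -0.0223 (-0.0264 to -0.0152) in AsPC-1, which argues against shared noise as its whole cause, and -0.0105 (-0.022 to 0.00136) in COLO-357, which does not decide. Set against the other line's vehicle change, the value nearer 0 was -0.035, which decides nothing. Treated cultures held at an earlier state, such as a lower density, may also contribute, but the correlation at 24 h exceeded that at 72 h by only 0.022 in 1 line and 0.17 in the other.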

How the results depend on the processing

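Leaving out COLO-357 replicate 2 in all groups, the block within a line for vehicle cultures, the restriction to members named through the other line, and the medians of line-difference lists in other scaling were chosen after the data were seen. The other alternatives were planned. Over 31 results and 589 alternatives, 501 kept their side of the threshold (for counts, stayed within 1.5 times) and 88 did not. Direction was compared only where the main fit or the alternative passed the threshold. Among those, no list result of the 31 and, over 4350 alternatives, no single named gene reversed its direction. For the 24 h line difference, however, the replication median went from 0.28 to -0.01 in the authors' scaled values. Counts have no direction of their own, and their balance did turn under several alternatives. The cause was not tested unless stated.

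With the authors' scaled values COLO-357 at 72 h had 5873 probes, the difference between times 450 in AsPC-1 and 1212 in COLO-357, the difference between lines 361 at 24 h and 2989 at 72 h, and the epithelial list in COLO-357 at 24 h adjusted p = 0.059. With 75th percentile scaling the time difference in AsPC-1 had 466, the vehicle change in AsPC-1 307, and the epithelial list in COLO-357 at 24 h adjusted p = 0.051. In the authors' scaled values probes moving up and down went from 1420 and 1371 to 734 and 5139 for COLO-357 at 72 h, from 310 and 146 to 208 and 1004 for its time difference, from 102 and 73 to 85 and 276 for the line difference at 24 h, from 477 and 359 to 305 and 2684 at 72 h, and from 2420 and 1938 to 2208 and 3036 for the COLO-357 vehicle change. With 75th percentile scaling the baseline went from 6889 and 6035 to 6655 and 10296. An offset of 50 gave 304 for the line difference at 24 h.

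The fit of all arrays shares 1 spread per probe between groups. AsPC-1 vehicle cultures at 24 h had a median SD of 0.248 log2, against 0.15 to 0.172 in the other groups. Contrasts with that group may thus be called too freely in the shared fit. Fitting only the groups compared uses their own spread but leaves fewer arrays to estimate it, and which of these mattered was not tested. It gave 674 probes for AsPC-1 at 24 h, 230 higher and 444 lower against 1468 and 1432, 961 at 72 h, 365 for its time difference, 41 for the line difference at 24 h and 3 for the vehicle change in AsPC-1, and adjusted p = 0.37 for the epithelial list in AsPC-1 at 72 h. A replicate block gave 324 for the line difference at 24 h and changed the call of no other count or list. Among values of named genes the block (pairing) lifted 3 over the threshold, SNAI2 in COLO-357 at 24 h among them (adjusted p = 0.041), and 1 lost its call, BRCA1 in COLO-357 at 72 h (adjusted p from 0.046 to 0.051). It changed no other named call. Array weights, which gave AsPC-1 vehicle replicate 1 at 24 h a weight of 0.214, gave 4413 (2249 higher and 2164 lower, against 1366 and 1430) and 4823 (2347 and 2476, against 1420 and 1371) for COLO-357 at 24 h and 72 h, turned AsPC-1 at 24 h to 931 higher and 1104 lower, and gave 1239 for the COLO-357 time difference, 1719 for the line difference at 72 h, and 350 and 6566 for the vehicle changes. Without the 4 arrays of COLO-357 replicate 2 its time difference had 259 and its vehicle change 2480.

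Stricter thresholds lower counts by construction. At an adjusted p under 0.01 the drug effects had 1483, 693, 1523 and 1451 probes (AsPC-1 at 24 h and 72 h, then COLO-357), the time differences 343 and 144, the line differences 43 and 309, and the vehicle changes 144 and 2240. In AsPC-1 at 24 h these were 645 higher and 838 lower. At 2-fold or more the drug effects had 614, 357, 554 and 400, the COLO-357 time difference 267, the line differences 111 and 462, the vehicle changes 128 and 541, and the baseline 5696.

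Leaving out 1 array gave 1966 to 3066 probes for AsPC-1 at 24 h, 831 to 1317 at 72 h, 1840 to 2197 for COLO-357 at 24 h and 1705 to 2998 at 72 h. The time differences ranged from 489 to 1022 and from 271 to 559, the line differences from 70 to 267 and from 485 to 930, the vehicle changes from 145 to 861 and from 2799 to 3833, and the baseline from 11830 to 13099. The adjusted p of the mesenchymal list in AsPC-1 at 24 h ranged from 0.015 to 0.09, that of the epithelial list from 0.025 to 0.59, and in COLO-357 from 0.021 to 0.056. Of 270 called values of named genes, 227 kept their call in every such fit and 43 did not.

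With an estimated correlation camera gave adjusted p = 0.085 for the mesenchymal list in AsPC-1 at 24 h. In AsPC-1 at 72 h it gave 0.15 for replication, 0.1 for mitosis and 0.1 for the epithelial list. In COLO-357 it gave 0.091 for the epithelial list and 0.056 for TGF-beta targets at 24 h, and 0.15 for replication and 0.078 for mitosis at 72 h. Fry gave 0.019 for the epithelial list in AsPC-1 at 24 h. With members named through the other line, AsPC-1 had 0.4 and 0.15 for the mesenchymal list at 24 h and 72 h and 0.64 for the epithelial list at 72 h. The mitosis and replication calls at 24 h in both lines held under every alternative run.

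A block by beadchip was not run, as chip positions were not used here, and a block nested in time gives no value for the vehicle or baseline contrasts. Averaging probes was run for named genes only. Genes at background in a group limit a fold to a lower bound.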
